A study of Homo sapiens with 12 samples.

How the data were processed

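RNA of HAEC from 12 arrays was compared, 4 arrays each for control gas, intermittent hypoxia and chronic hypoxia. Groups and replicate numbers came from the sample titles and the gas settings from the series' design text. The control titles name no treatment and were matched to the control gas through that text. The platform is a human Illumina bead array per the series' design text; a protocol in the labels names a mouse chip, while the probe annotation used here is human.

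The values are a score per probe and array as the authors deposited them, with 12 value columns and 6237 probes, no missing values and a range from -1.85 to 7.24. BeadStudio is named in the submitters' processing notes, without a version. From the values, each array appears to have been standardised after a log transform, but the log base, the probes over which it was standardised and the selection of the 6237 probes are not given in the sources used here. Over the table, array means ran from 0.358 to 0.519, array medians from -0.0902 to 0.0957 and array SDs from 1.31 to 1.57, so the arrays are not on exactly the same scale over these probes. A score difference is therefore not a fold, and its size depends on the spread of each array. Low probes shifted upward and bright probes downward against control: in intermittent hypoxia the median difference was 0.171 in the lowest 25% of probes by level and -0.0763 in the highest 25%. Detection p-values and background were not used here, so signal over background is unknown.

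Gene symbols came from the platform annotation. Of the 6237 probes 5507 carry 1 symbol, 0 carry several and 730 carry none here. For gene counts, lists and named genes the probe with the highest mean over the 12 arrays stood for the gene, which matters for 123 genes. Of 36 genes with several probes and a call in intermittent hypoxia, all probes were called in 14, and 1 gene had probes called in opposite directions. In chronic hypoxia all probes were called in 5 of 20 such genes, and 2 genes had opposite calls. No genome build is stated, so no coordinates are given.

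The design had been written for log2 intensities with the provision that values already standardised are used as they are, and that was done, with no pseudocount. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 12 arrays, which share an estimate of the spread, with eBayes without a trend and Benjamini-Hochberg adjustment over 6237 probes at 0.05. Simulated data were made from the spread of each probe on these arrays, with 200 of 6237 probes shifted. The fit of intermittent hypoxia against control recovered 2.4% of shifts of 0.25 score units and 29.7% of shifts of 0.5. It recovered 88.6% of shifts of 1 and 99.6% of shifts of 2, with 4.51% false calls. The simulated noise was independent between probes. On the real arrays the first component of the deviations from group means held 35.4% of their variance, so these rates may not carry over. Gene lists were fixed before the data were examined: 20 lists, of which 18 had at least 3 measured genes and were tested. limma's camera compared each list with the other genes with a preset inter-gene correlation of 0.01, and with an estimated correlation no list was called in any comparison. fry tested whether list members changed in one direction or in either. List medians were also set against 10000 random lists matched on mean level. Matching of older symbols changed 0 names.

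Genes named in the text followed a rule fixed before the data were examined. They are, for each comparison with control, the 8 largest increases and 8 largest decreases among called genes whose groups do not overlap. Added to these were up to 3 called members of each list with the smallest adjusted p. A further 26 genes were named whatever their result, of which 14 were measured. Measured means here that a probe with the gene's symbol is among the 6237. Between the hypoxic groups, where no gene passed, the 6 with the smallest unadjusted p were named. The rule gave 64, 60 and 6 genes, and the text says where a gene was named outside it. Genes of the sex chromosomes that would reveal a donor's sex were left out of the named genes.

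The alternatives were quantile normalization, median centring, rescaling of each array, filters on mean level, a replicate block, a fit of the compared groups alone, an intensity trend, array weights, thresholds of 0.01 and 0.1, leaving out each array, an estimated correlation and the mean of a gene's probes. Rescaling, leaving out control array 2 together with intermittent array 3, and a covariate from the arrays' deviations were added after seeing the data. An offset for linear intensities does not apply to standardised values and was not run. Permutation tests were exact and two-sided. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.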

Results

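Gene expression was measured in HAEC, primary endothelial cells of the human aorta, the cells that line the inner wall of that artery. Cultures were kept for 8 h in 1 of 3 gas conditions, each with 5% CO2. Control cells stayed at 16% O2, chronically hypoxic cells stayed at 4% O2, and intermittently hypoxic cells alternated between 5 min at 16% O2 and 5 min at 0% O2. Each condition had 4 arrays, 12 in all, of an Illumina bead array for human transcripts. The table holds 6237 probes, of which 5507 carry 1 gene symbol and stand for 5376 genes. Levels are standardised scores per array, from -1.85 to 7.24, whose log base and reference probes are not given in the sources used here, so differences are given in score units and not as folds. Correlations between arrays over all probes ran from 0.951 to 0.988 within groups and from 0.928 to 0.986 between groups. The labels do not say that arrays of 1 group came from separate cultures, so p-values measure the spread between these arrays, which may be technical, and the number of arrays limits the precision. The median standard error of a difference was 0.156 score units.

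The first comparison asks which transcripts differed after 8 h of intermittent hypoxia. The largest change was the loss of the stress-inducible chaperone HSPA6, from 3.52 ± 0.90 in control to -0.84 ± 0.33 (SD, n = 4 arrays each) in intermittent hypoxia. HSPA1A, an inducible HSP70, fell from 4.18 ± 0.52 to 2.01 ± 0.35, and its co-chaperone DNAJB1 from 2.83 ± 0.96 to 0.76 ± 0.14. The largest increases of genes with a symbol included SLC38A2, a neutral amino acid transporter (difference 2.08, SE 0.205), HSP90B1, the HSP90 of the endoplasmic reticulum (1.94, SE 0.238), and HMOX1, the haem-degrading enzyme haem oxygenase 1 (1.88, SE 0.284). limma called 1226 of 6237 probes (adjusted p under 0.05), 840 higher and 386 lower, or 1060 genes with 739 higher and 321 lower. The 68.5% share of higher probes followed the scaling of the arrays: quantile normalization gave 627 higher and 594 lower, rescaling each array to mean 0 and SD 1 gave 635 and 567, and median centring gave 541 and 662. The called probes changed as well. Of the 1226, quantile normalization kept 937 in the same direction, rescaling 961 and median centring 927. The count of called probes was 808 without control array 1, 660 without control array 3, 749 without intermittent array 1 and 767 without intermittent array 4.

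Other genes with the largest increases were FILIP1L (difference 1.95, SE 0.170, limma adjusted p = 2.37e-06), the Wnt antagonist DKK1 (1.67, SE 0.170, adjusted p = 1.61e-05), the cytosolic chaperone HSP90AA1 (1.67, SE 0.252, adjusted p = 0.000491), the zinc finger gene ZSCAN31 (1.63) and the phospholipid-binding protein ANXA1 (1.57). A second probe of FILIP1L rose by 0.59 and one of ZSCAN31 by 1.01. Among the largest decreases, TENT5A, a noncanonical poly(A) polymerase, fell from 1.62 ± 0.29 to -0.20 ± 0.19 (SD, n = 4 arrays each). ZNF417 fell by 1.44, DIP2B by 1.33, SLX1B by 1.30 and the phosphatase CDC14B by 1.29. SLX1B has a near-identical copy in the genome, so its level may include that of the copy and is uncertain. In each of these genes all 4 intermittent arrays lay on one side of all 4 control arrays, as the naming rule required. Over all 6237 probes this held for 17.0%, where chance alone gives 2.86%. It held for 829 of the 1226 called probes, which were selected by the test.

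**Figure D1:**
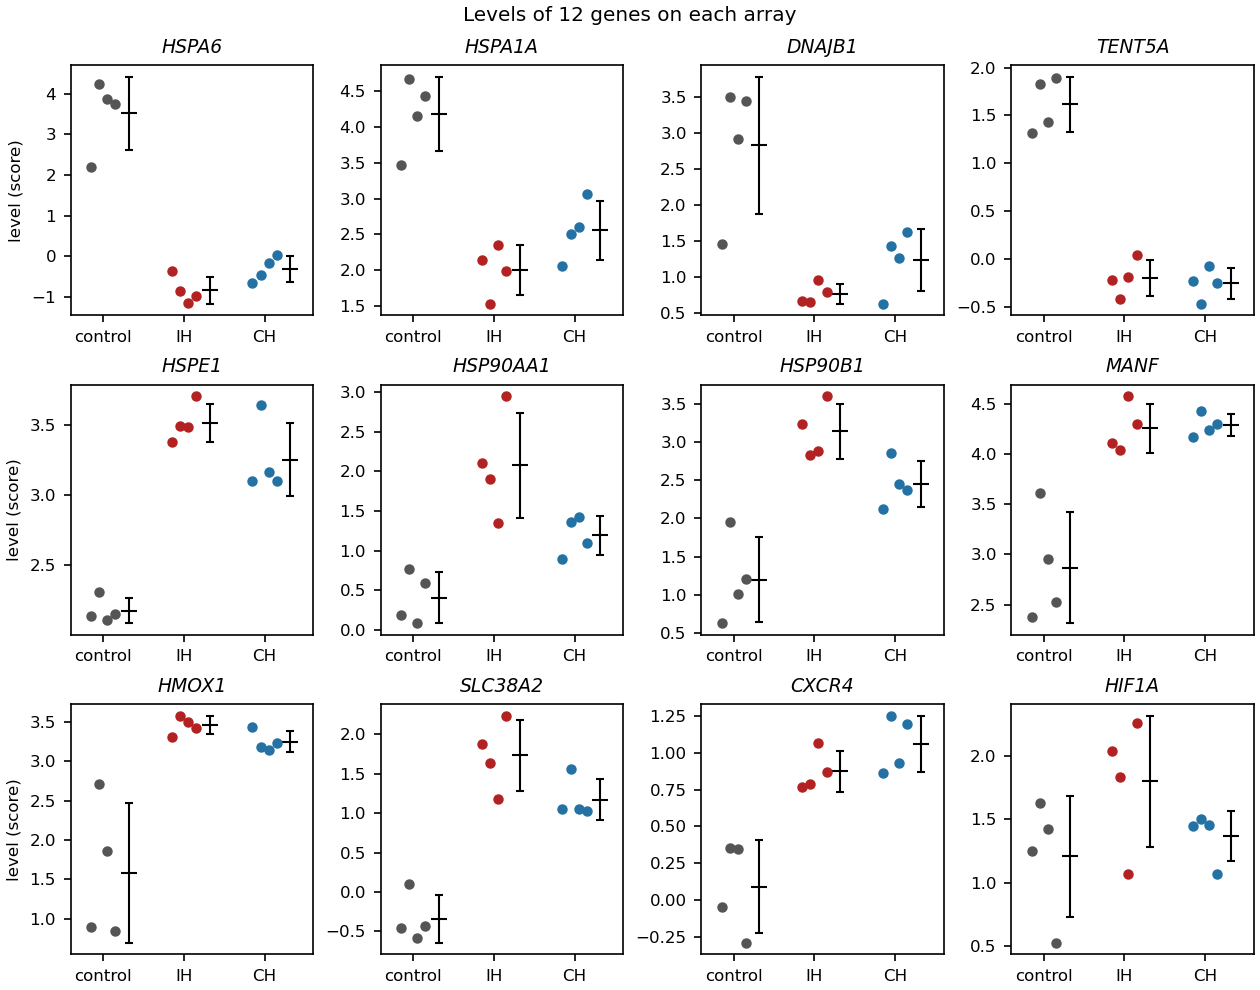
Levels in score units (vertical axes, scaled separately) of 12 genes on each array of control, intermittent hypoxia (IH) and chronic hypoxia (CH), with points for arrays and bars for the mean and SD of 4 arrays. HSPA6, HSPA1A and TENT5A lay lower on all hypoxic than on all control arrays; for DNAJB1 1 control array, at 1.46, overlapped the chronic group, and HIF1A overlapped between all groups.

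Of 23 measured genes of the unfolded protein response, 8 rose in intermittent hypoxia, 1 fell and 14 did not pass (10 and 1 adjusted over the list alone). Those that rose included HSP90B1, the BiP co-chaperone DNAJB11 (1.26, SE 0.189) and the secreted trophic factor MANF (1.38, SE 0.210). The gene that fell was PPP1R15A (-0.78, SE 0.225), a regulator of eIF2alpha phosphatase, named after its value was seen. The list median was 0.53, and camera called the list higher (adjusted p = 0.0049), with adjusted p = 0.453 with an estimated correlation. The 15 heat shock genes split: 4 rose and 4 fell, the same counts as adjusted over the list alone. HSPE1, the mitochondrial co-chaperonin, rose from 2.17 ± 0.09 to 3.52 ± 0.14 (SD, n = 4 arrays each). HSP90AA1 rose with it, as did HSPB1 (1.16, SE 0.201) and HSPD1 (1.08, SE 0.302), while BAG3 (-1.11, SE 0.337) fell with HSPA6, HSPA1A and DNAJB1. HSPB1, HSPD1 and BAG3 were named after their values were seen. The probe of HSPA1B, a near copy of HSPA1A, was low in control (-0.41 ± 0.22) and did not pass the test (0.19, adjusted p = 0.459), so the paralogs cannot be separated with certainty. The heat shock list had a median of 0.34, a mean of -0.16 and no camera call (adjusted p = 0.948), and fry found change in either direction (adjusted p = 2.01e-08). Change in either direction was not particular to this list. For other lists without a camera call fry gave adjusted p = 1.71e-06 for p53 targets and 9.99e-06 for cholesterol synthesis. Only the metallothionein, respiratory chain and smooth muscle lists did not pass that test. The directions given above for HSPA6, HSPA1A, DNAJB1, HSPE1, HSPB1 and HSP90AA1 were called under quantile normalization, median centring and rescaling as well.

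Of 18 measured hypoxia response genes, 6 rose and none fell (6 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.196; 0.492 with an estimated correlation). CXCR4, a chemokine receptor, rose by 0.78 (SE 0.159), the collagen prolyl hydroxylase P4HA1 by 0.87 (SE 0.176) and WSB1 by 0.65 (SE 0.189). Several well-known targets of hypoxia-inducible factor that were named whatever their result gave no call. The difference was 0.14 for ADM (adjusted p = 0.521), 0.17 for BNIP3 (0.421) and 0.05 for NDRG1 (0.876). It was 0.12 for PGK1 (0.592) and -0.37 for LDHA (0.377). ADM and PGK1 lay low on the control arrays, at -0.69 to -0.24 and -0.54 to -0.06, with signal over background unknown. VEGFA, SLC2A1, PDK1, EGLN3 and ANGPTL4 were to be named in the same way but had no probe among the 6237. The selection of these probes is not given, so whether the array assayed those genes is unknown here. HIF1A itself differed by 0.59 on its brightest probe (adjusted p = 0.0899) and by 0.23 on its other probe (0.256). The brightest probe of HIF1A was called higher in 6 of 26 other settings, among them the fits without intermittent array 3 (adjusted p = 0.00774) or control array 2 (0.0384). LDHA was called lower with array weights (adjusted p = 0.0363) and without both of these arrays (-0.89, adjusted p = 0.00257). Of 8 oxygen sensing components, CITED2, an inhibitor of HIF transactivation, rose by 1.08 (SE 0.219) and the prolyl hydroxylase EGLN2 by 0.44 (SE 0.130), 2 calls against 5 adjusted over the list alone; the list was not called (adjusted p = 0.196). Of 13 glycolysis genes, 3 fell (5 adjusted over the list alone): PFKP (-0.92, SE 0.198), a phosphofructokinase, the glucose transporter SLC2A3 (-0.69, SE 0.222) and ENO1 (-0.46, SE 0.140). The glycolysis list was called lower (median -0.36, camera adjusted p = 0.0049), with adjusted p = 0.375 with an estimated correlation and 0.0701 under quantile normalization. Leaving out 1 array ended the calls of ENO1 (adjusted p = 0.0835 without intermittent array 1), SLC2A3 (0.106 without intermittent array 2), WSB1 (0.0847 without intermittent array 1) and EGLN2 (0.0762 without control array 3), and each of the 3 scalings ended that of EGLN2. Quantile normalization and rescaling ended the call of ENO1, and median centring that of WSB1.

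Immediate early genes rose, 7 of 13 with none lower, the same count as adjusted over the list alone. IER3 rose by 1.39 (SE 0.167), the matricellular gene CCN2 by 0.89 (SE 0.189) and IER2 by 0.73 (SE 0.156), with a camera adjusted p of 0.0196 for the list and an adjusted p = 0.375 with an estimated correlation. Of 13 angiogenesis genes 5 rose (6 adjusted over the list alone), among them THBS1, an inhibitor of vessel growth, by 0.88 (SE 0.158), CXCR4, and the arterial ephrin EFNB2 by 0.50 (SE 0.125). That list was called (adjusted p = 0.0279), with adjusted p = 0.375 with an estimated correlation and 0.0844 without intermittent array 3. Of 10 p53 target genes 5 rose and 1 fell (6 and 2 adjusted over the list alone), with GDF15 1.00 and PLK3 0.78 higher and TP53I3 -0.68 lower, and no list call (adjusted p = 0.167). Of 20 oxidative stress genes 4 rose (5 adjusted over the list alone), including HMOX1, the autophagy receptor SQSTM1 (0.67, SE 0.154) and OSGIN1 (0.67, SE 0.162), with no list call (adjusted p = 0.268). Under quantile normalization the immediate early list had an adjusted p of 0.0701 and so did the angiogenesis list, so neither was called there.

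Of 9 measured NF-kB and inflammatory genes NFKBIA, the inhibitor that NF-kB induces, rose by 0.88 (SE 0.170), 1 call against 3 adjusted over the list alone. The list had a median of 0.30 and was not called by camera (adjusted p = 0.346). By contrast fry, which tests the list by itself, gave an adjusted p of 0.0425 for higher levels. This was not particular to the list. For other lists without a camera call fry gave adjusted p = 0.0107 for hypoxia response, 0.0107 for oxygen sensing and 0.00182 for p53 targets. CXCL8 differed by 0.65 (adjusted p = 0.0533), VCAM1 by 0.50 (0.0682) and CCL2 by -0.27 (0.195), none past the threshold. Other settings called CXCL8 higher in 9 of 26, among them quantile normalization (adjusted p = 0.0414) and the fits without control array 4 (0.0151) or intermittent array 2 (0.0147). They called VCAM1 higher in 6 of 25, among them the fit without control array 2 (0.00359). Array weights called CCL2 lower (adjusted p = 0.0236). NOS3, the endothelial nitric oxide synthase (-0.06), EDN1, endothelin 1 (-0.004), SOD2 (-0.004) and PECAM1 (-0.27) gave no call either. NOS3 and SOD2 lay low on the control arrays, at -0.68 to -0.52 and -0.86 to -0.57. Their signal over background is unknown, so a fall might not show. The difference of EDN1 rests on intermittent array 3, at 3.57 against 1.88 to 2.29 on the other intermittent arrays. Without that array it was -0.37 (adjusted p = 0.0787). That of PECAM1 ran from -0.51 to -0.10 with 1 array left out. Without control array 2 and intermittent array 3 together it was -0.71 (adjusted p = 0.0343). Of 21 endothelial markers 4 rose and 3 fell (4 and 4 adjusted over the list alone), with the transcription factor SOX17 (0.76, SE 0.139) and MMRN1 (1.32, SE 0.258) higher and ICAM2 (-0.71, SE 0.151) lower, and no list call (adjusted p = 0.346). Of 10 interferon response genes IFI35 fell (-0.81, SE 0.197; the same count adjusted over the list alone), and the list was not called (adjusted p = 0.129). Of 17 cholesterol and fatty acid synthesis genes SCD, a desaturase, rose by 0.88 (SE 0.184) and FDPS, an enzyme of isoprenoid synthesis, fell by 0.83 (SE 0.148), again the same counts adjusted over the list alone, with no list call (adjusted p = 0.346). Of 13 proliferation genes 2 fell, the replication licensing genes MCM7 (-0.75, SE 0.135) and MCM5 (-0.43, SE 0.140), against 3 adjusted over the list alone (camera adjusted p = 0.196, median 0.02 and mean -0.04). The call of MCM5 was lost without control array 3 (adjusted p = 0.133) and in 9 of the 12 fits that left out 1 array.

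A further 3 lists were called lower in intermittent hypoxia on few called members. Of 4 metallothionein genes MT1X fell (-0.62, SE 0.165; adjusted p of the list = 0.0216, and adjusted p = 0.375 with an estimated correlation), 1 call adjusted over the list alone too. Of 11 vascular tone and coagulation genes 2 fell, the urokinase receptor gene PLAUR (-0.69, SE 0.150) and the coagulation inhibitor TFPI (-0.51, SE 0.140), again 2 adjusted over the list alone (list adjusted p = 0.0259, and adjusted p = 0.453 with an estimated correlation). Of 31 respiratory chain genes 2 fell, NDUFA9 (-0.44, SE 0.136) and ATP5F1B (-0.47, SE 0.157), and 0 adjusted over the list alone (list adjusted p = 0.0153, and adjusted p = 0.492 with an estimated correlation). Under quantile normalization these lists had adjusted p values of 0.0889, 0.0701 and 0.266, and none was called. Without control array 3 the metallothionein list and the vascular list both had an adjusted p of 0.0573, without intermittent array 3 the metallothionein list had 0.0844, and without intermittent array 1 the respiratory chain and vascular lists both had 0.0587. Leaving out 1 array also ended the calls of MT1X (adjusted p = 0.0519 without control array 3), TFPI (0.0574 without intermittent array 2), NDUFA9 (0.117 without control array 3) and ATP5F1B (0.136 without intermittent array 1), and quantile normalization and rescaling that of ATP5F1B.

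The second comparison asks the same of chronic hypoxia. HSPA6 was again the gene with the largest change, at -0.31 ± 0.31 in chronic hypoxia against 3.52 ± 0.90 in control (SD, n = 4 arrays each), with TENT5A at -0.26 ± 0.16 against 1.62 ± 0.29 and HSPA1A at 2.56 ± 0.41 against 4.18 ± 0.52. The largest increases of genes with a symbol were HMOX1 (1.67, SE 0.284), the adenosine receptor ADORA2A (1.57, SE 0.164), IER3 (1.54, SE 0.167), SLC38A2 (1.52, SE 0.205) and the HSP90 co-chaperone FKBP4 (1.49, SE 0.221), followed by FILIP1L (1.43), MANF (1.42) and DKK1 (1.41). The second probe of FILIP1L differed by 0.37 and did not pass the test (adjusted p = 0.101). Further large decreases were those of ZNF417 (-1.57), DIP2B (-1.42), SLX1B (-1.39), the tubulin pseudogene TUBA3FP (-1.34), whose probe may also report related tubulins, and NXPE2 (-1.24). limma called 735 of 6237 probes, 434 higher and 301 lower, or 624 genes with 379 higher and 245 lower. The 59.0% share of higher probes also depended on scaling, with 342 higher and 425 lower after median centring, 358 and 372 after rescaling and 378 and 348 after quantile normalization. Of the 735 called probes, median centring kept 643 in the same direction, rescaling 611 and quantile normalization 595. The count of called probes was 400 without control array 3, 470 without chronic array 1, 388 without chronic array 2 and 392 without chronic array 4.

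Of the 23 unfolded protein response genes 9 rose in chronic hypoxia, 1 fell and 13 did not pass (10 and 1 adjusted over the list alone), with MANF, HSP90B1 (1.25, SE 0.238) and DNAJB11 (0.88, SE 0.189) higher and PPP1R15A (-0.77, SE 0.225) lower. The list had a camera adjusted p of 0.000415 and an adjusted p = 0.329 with an estimated correlation. Of 15 heat shock genes 3 rose and 3 fell (4 and 3 adjusted over the list alone). HSPE1 rose by 1.08 (SE 0.142), and HSPB1 by 1.18 (SE 0.201) and HSP90AB1 by 0.79 (SE 0.221), both of them named after their values were seen, while DNAJB1 (-1.60, SE 0.326) fell with HSPA6 and HSPA1A. That list was not called (camera adjusted p = 0.850, median 0.23, mean -0.12), and fry found change in either direction (adjusted p = 4.65e-08). Again this was not particular to the list. For other lists without a camera call fry gave adjusted p = 8.05e-06 for p53 targets and 3.63e-06 for endothelial markers. The metallothionein, respiratory chain and smooth muscle lists alone did not pass it.

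Of 18 hypoxia response genes 3 rose and none fell (5 adjusted over the list alone) in chronic hypoxia: CXCR4 by 0.97 (SE 0.159), the histone demethylase KDM4B by 0.73 (SE 0.165) and NDRG1 by 0.57 (SE 0.167). The list was called (median 0.25, camera adjusted p = 0.0266), with adjusted p = 0.329 with an estimated correlation and 0.0509 without chronic array 4. ADM differed by 0.41 (adjusted p = 0.0730), PGK1 by 0.17 (0.496), BNIP3 by -0.11 (0.680), LDHA by -0.25 (0.627) and HIF1A by 0.16 on its brightest probe (0.729), none past the threshold. ADM was called higher in 5 of 25 other settings, among them the fits without control array 4 (adjusted p = 0.0469) or chronic array 3 (0.0381). LDHA was called lower without control array 2 and intermittent array 3 together (-0.55, adjusted p = 0.0485). CITED2 rose by 1.25 (SE 0.219) and EGLN2 by 0.45 (SE 0.130), the same 2 of 8 oxygen sensing components as adjusted over the list alone, with no list call (adjusted p = 0.541). Of 13 glycolysis genes PFKP fell (-0.69, SE 0.198; 2 adjusted over the list alone), and of 31 respiratory chain genes NDUFV1 fell (-0.53, SE 0.158; 0 adjusted over the list alone). Both lists were called lower (camera adjusted p = 0.0266 and 0.00767), with adjusted p = 0.329 and 0.488 with an estimated correlation, and with 0.186 and 0.237 under quantile normalization. Leaving out 1 array ended the calls of NDRG1 (adjusted p = 0.114 without chronic array 4), EGLN2 (0.0925 without chronic array 3), PFKP (0.116 without control array 3) and NDUFV1 (0.114 without control array 3). Each of the 3 scalings also ended that of EGLN2, and quantile normalization and rescaling that of NDUFV1.

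Of 13 immediate early genes 7 rose in chronic hypoxia (7 adjusted over the list alone), with IER3, CCN2 (0.93, SE 0.189) and JUND (0.84, SE 0.188) as the leading members (camera adjusted p = 0.00074, and adjusted p = 0.253 with an estimated correlation). Of 13 angiogenesis genes 4 rose (5 adjusted over the list alone), with CXCR4, the lymphangiogenic factor VEGFC (0.65, SE 0.163) and NOTCH1 (0.54, SE 0.170) named here, and the list was called (adjusted p = 0.0266, and adjusted p = 0.329 with an estimated correlation). The call of NOTCH1 was lost in 10 of the 12 fits that left out 1 array (adjusted p = 0.146 without control array 1) and under each of the 3 scalings, and that of VEGFC in 2 fits (0.0659 without chronic array 2). Of 10 p53 target genes 4 rose and 1 fell (4 and 2 adjusted over the list alone), with GDF15 (1.13, SE 0.169) and the cell cycle inhibitor CDKN1A (0.54, SE 0.137) higher and ZMAT3 (-0.74, SE 0.182) lower, and no list call (adjusted p = 0.274). Of 20 oxidative stress genes HMOX1, SQSTM1 (0.66, SE 0.154) and the ferritin light chain FTL (0.53, SE 0.157) rose, the same 3 adjusted over the list alone, with a camera adjusted p of 0.0728, and 0.0404 under quantile normalization. Without 1 array the calls of CDKN1A (adjusted p = 0.0712 without chronic array 4), ZMAT3 (0.0558 without chronic array 4) and FTL (0.123 without chronic array 2) were lost, as were those of ZMAT3 under quantile normalization and rescaling and of FTL under median centring.

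NFKBIA rose by 1.00 (SE 0.170) in chronic hypoxia, the 1 call among 9 NF-kB and inflammatory genes (1 adjusted over the list alone; camera adjusted p = 0.850, median -0.06 and mean 0.09). CXCL8 (-0.15), CCL2 (-0.24), VCAM1 (0.14), NOS3 (0.005), EDN1 (0.32), SOD2 (0.16) and PECAM1 (-0.36) gave no call. NOS3 and SOD2 lay low on the chronic arrays too, at -0.75 to -0.38 and -0.62 to -0.53, with signal over background unknown. Of 21 endothelial markers SOX17 (0.80, SE 0.139) and SOX18 (0.74, SE 0.174) rose and ICAM2 (-0.71, SE 0.151) fell, 2 and 1 against 3 and 3 adjusted over the list alone (camera adjusted p = 0.850). Of 10 interferon response genes IFI35 (-0.94, SE 0.197) and RSAD2 (-0.62, SE 0.195) fell, against 3 adjusted over the list alone (camera adjusted p = 0.121). Of 17 cholesterol and fatty acid synthesis genes SCD rose by 0.83 and FDPS fell by 0.73 (the same adjusted over the list alone; camera adjusted p = 0.513), and of 13 proliferation genes MCM7 (-0.73) and MCM5 (-0.48) fell (2 adjusted over the list alone; camera adjusted p = 0.160). PLAUR (-0.74, SE 0.150) and TFPI (-0.56, SE 0.140) fell among 11 vascular tone and coagulation genes (2 adjusted over the list alone; camera adjusted p = 0.211). MT1X fell (-0.70, SE 0.165) among 4 metallothionein genes (1 adjusted over the list alone), and that list was called lower (camera adjusted p = 0.0266, and adjusted p = 0.329 with an estimated correlation), with 0.0673 under quantile normalization and 0.101 without control array 3. Leaving out 1 array ended the calls of RSAD2 (adjusted p = 0.146 without chronic array 4), MCM5 (0.116 without control array 3), TFPI (0.0550 without chronic array 2) and MT1X (0.0510 without chronic array 2), and quantile normalization ended that of RSAD2.

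**Figure D2:**
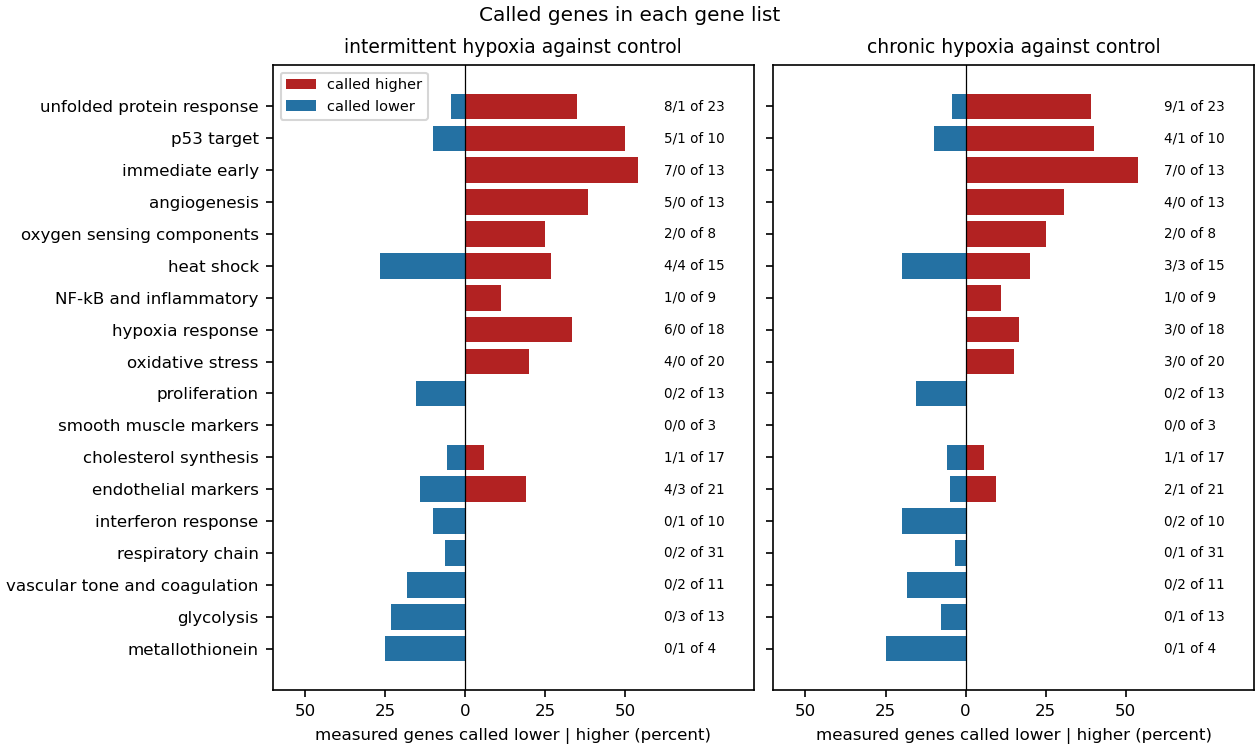
Percent of each list's measured genes that limma called higher (red, to the right) or lower (blue, to the left) in intermittent hypoxia against control and in chronic hypoxia against control, with the counts of higher and lower genes beside the bars. In the unfolded protein response list 8 of 23 genes rose in intermittent and 9 of 23 in chronic hypoxia, while the heat shock list had 4 higher and 4 lower in the first and 3 and 3 in the second.

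Markers of other cell types were few, so a shift in the make-up of the cultures cannot be excluded. The median level of 21 endothelial markers was 1.20 ± 0.14 in control, 1.46 ± 0.23 in intermittent and 1.20 ± 0.43 in chronic hypoxia (SD, n = 4 arrays each), near the 77th to 81st percentile of all probes. For 3 smooth muscle markers it was 1.71 ± 0.08, 1.71 ± 0.21 and 1.80 ± 0.23, with 0 of 3 called (0 adjusted over the list alone) and camera adjusted p values of 0.682 and 0.850. The 1 measured fibroblast marker differed by 0.71 in intermittent hypoxia, where it was not called over all probes (adjusted p = 0.0961). Its unadjusted limma p was 0.0265, which adjustment over a list of 1 gene leaves as it is. Of all probes, 34.4% had an unadjusted p under 0.05 in that comparison. In chronic hypoxia the marker differed by 0.17 and passed neither with nor without adjustment. No leukocyte marker was among the probes used here. The smooth muscle and fibroblast markers lay near the 83rd to 85th and the 78th to 85th percentile, as high as the endothelial markers. These levels therefore do not set endothelial cells apart. Of the fixed lists, 21 of 25 endothelial, 3 of 14 smooth muscle, 1 of 13 fibroblast and 0 of 17 leukocyte markers had a probe here. The selection of the probes is not given, so it is unknown whether these shares reflect expression.

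The third comparison asks whether intermittent and chronic hypoxia differed from each other. These groups differed in the O2 levels set for the gas as well as in the pattern over time. The comparison therefore cannot separate an effect of the pattern from one of the O2 level. limma called 0 of 6237 probes between intermittent and chronic hypoxia, with 407 probes, 6.53%, at an unadjusted p under 0.05 and a smallest adjusted p of 0.749. The 6 genes with the smallest unadjusted p, none past the threshold, were all higher in intermittent hypoxia: GTF2F2, a subunit of transcription factor IIF (0.69, SE 0.176), the nuclear import receptor KPNB1 (0.63, SE 0.173), MRPL47 (0.57, SE 0.156), BZW1 (0.56, SE 0.158), EIF2S2, a subunit of the initiation factor eIF2 (0.54, SE 0.154), and FASTKD2 (0.52, SE 0.134). The second probe of MRPL47 differed by 0.25. camera called 0 of 18 lists, the smallest adjusted p being 0.168 for the glycolysis list and for the vascular tone and coagulation list, both with lower medians in intermittent hypoxia (-0.05 and -0.07). The median half-width of the 95% interval of a difference was 0.327 score units, before adjustment over probes, and the adjusted test detects only larger differences. limma with array weights called 347 probes, and 0 under quantile normalization, median centring and rescaling. Without intermittent array 3 limma called 76 probes, GTF2F2 (adjusted p = 0.0350), BZW1 (0.0350), FASTKD2 (0.0350) and MRPL47 (0.0497) among them, and camera called the vascular tone and coagulation list lower (adjusted p = 0.0259).

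The differences of the intermittent and chronic groups from control were set against each other across probes. Of the probes called, 341 rose in both conditions and 235 fell in both, while no probe was called in opposite directions. The differences correlated with Pearson r = 0.873 across 6237 probes, which are not independent replicates. Because both differences use the same 4 control arrays, 1000 simulated pairs of unchanged groups gave a median r of 0.547, with 95% of values between -0.30 and 0.918, so r alone does not separate the data from chance. The covariance was 0.113 against a simulated median of 0.0126 with 95% of values between -0.006 and 0.0508. With the controls split so that each hypoxic group had 2 control arrays of its own, the 6 assignments gave r from 0.539 to 0.708 and a covariance from 0.0835 to 0.101. In these, 29 to 109 probes were called higher in both and 14 to 48 lower in both, and 0 were called in opposite directions. The mean overlap expected of independent lists of the same sizes was at most 9.72 higher and 4.61 lower over the 6 assignments.

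**Figure D3:**
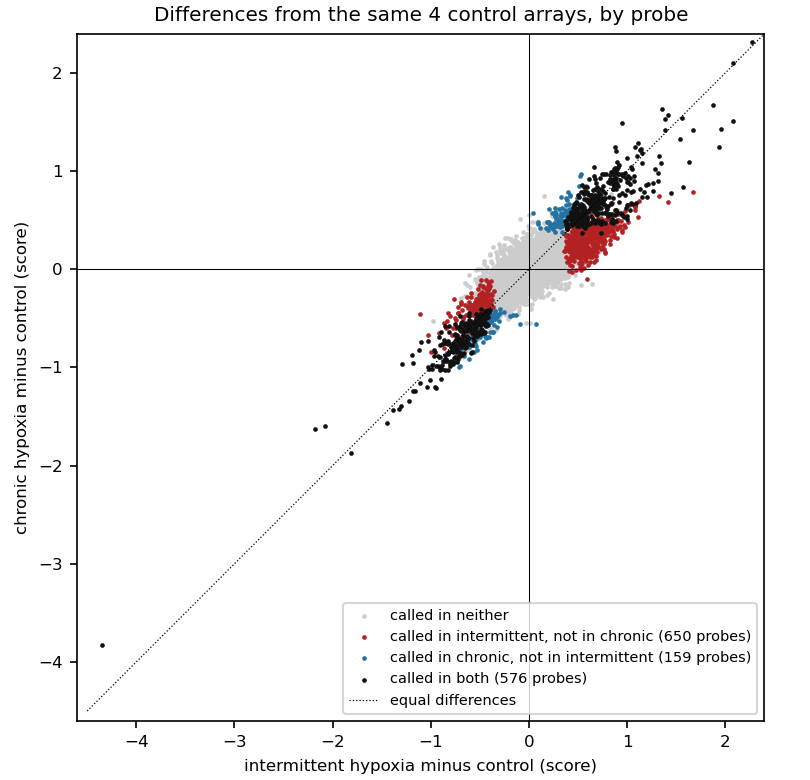
Difference of each probe from the 4 control arrays in score units, intermittent hypoxia on the horizontal and chronic hypoxia on the vertical axis, coloured by the limma calls, with a dotted line of equal differences. The 576 probes called in both conditions lie in the upper right and lower left, 650 were called in intermittent and not in chronic hypoxia and 159 the other way round, and HSPA6 stands alone at the lower left. The probes furthest to the upper right are among the 730 unnamed probes, of which 80 were called higher and 61 lower in intermittent and 46 and 54 in chronic hypoxia.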

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

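The tests of array scaling, of a general heat shock response and of level-matched lists were chosen after the results were seen; the test that left out each array was set before. Over 252 groups of 4 arrays of the named genes, 11 had 1 array far from the other 3 by Dixon's ratio, and chance alone gives about 12.6. They were ATP5F1B in control array 2 (ratio 0.849), JUND in control array 2 (0.938), OSGIN1 in control array 2 (0.860), NDUFV1 in control array 3 (0.897), CDC14B in intermittent array 3 (0.851), PFKP in intermittent array 3 (0.912) and RSAD2 in intermittent array 4 (0.850). In chronic hypoxia they were BNIP3 (0.980), HSPE1 (0.878) and SLC38A2 (0.962), all in array 2, and HIF1A in array 4 (0.871). For JUND the outlying control level was 4.49 against 3.54 to 3.60 on the other control arrays.

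HSPA6, HSPA1A and DNAJB1 fell while HSPE1, HSPB1 and HSP90AA1 rose in intermittent hypoxia, and a single array, the array scaling and a heat shock response of the control cultures were weighed as explanations. All 6 genes were called in the same direction with each of the 12 arrays left out in turn and under all 3 scalings, which argues against the first 2. A general heat shock response in the control cultures as the whole cause would put all 6 genes lower in hypoxia. The lower 95% limits of the differences of HSPE1, HSPB1 and HSP90AA1 were 0.73 or more. These genes were picked because they had been called higher, so their limits were bound to lie above 0 and are no test. They show only that such a response by itself would not give the rise of these genes. A part of such a response behind the fall of HSPA6, HSPA1A and DNAJB1 stays open, as does an effect of the gas conditions that the design names, and they were not separated, because each group had its own gas.

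More probes were called higher than lower against control, and the centre and spread of the standardised values is a candidate explanation. Under quantile normalization the share of higher probes was 51.4% in intermittent and 52.1% in chronic hypoxia, which is what that explanation predicts. A true excess of higher transcripts that quantile normalization removes stays open, since that method forces the arrays to the same distribution.

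Glycolysis and respiratory chain genes were called lower as lists, in intermittent hypoxia with adjusted p = 0.375 and 0.492 and in chronic hypoxia with 0.329 and 0.488 with an estimated correlation, and with no call under quantile normalization (0.0701 and 0.266, then 0.186 and 0.237). A downward shift of abundant genes could produce such calls. The glycolysis median in intermittent hypoxia lay at the 0.68th percentile of level-matched random lists, lower than most lists with only that shift. Random lists ignore the correlation between list members, estimated at 0.082 for glycolysis genes. The percentile therefore does not exclude the shift. In chronic hypoxia the glycolysis median lay at the 5.14th percentile, which leaves the shift open. The respiratory chain median in intermittent hypoxia lay at the 12.9th percentile and in chronic hypoxia at the 13.9th, within what the shift gives.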

How the results depend on the processing

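Array rescaling, the pair of arrays left out and the covariate were chosen after seeing the data; the other settings were set before. Of the named genes 51 were called in intermittent and 48 in chronic hypoxia, 41 and 34 of these in every setting in which their probe was tested (a filter on level removed some), and none reversed. The naming rule favours large differences and small adjusted p on these same arrays, so this does not measure how stable all calls are. Over all probes, 651 of the 1226 calls in intermittent hypoxia kept their direction without control array 3. In chronic hypoxia 388 of the 735 did so without chronic array 2. These were the fewest kept with 1 array left out. Leaving out 1 array gave 660 to 1676 calls in intermittent hypoxia (469 to 1042 higher, 191 to 634 lower), 388 to 948 in chronic hypoxia (240 to 559 higher, 143 to 389 lower) and 0 to 76 between them, where the 76 came without intermittent array 3. It gave 5 to 8, 7 to 8 and 0 to 1 lists, and r from 0.794 to 0.904. Below, values are for intermittent and then chronic hypoxia, and the cause was not tested unless stated. An adjusted p of 0.01 gave 484 (363 higher, 121 lower) and 280 (182 and 98) calls, and 0.1 gave 611 and 463 lower, by construction. Keeping the brighter of 2 equal parts of the probes gave 672 (393 higher) and 492 (258 higher) calls and 2 lists in each, with fewer probes tested. Quantile normalization gave 594 lower probes and 1 list in intermittent hypoxia, rescaling gave 1 list, and median centring gave 541 higher and 662 lower. An estimated correlation gave 0 lists in each. Array weights gave 2557 (1666 higher, 891 lower), 1657 (1018 and 639) and, between the hypoxic groups, 347. Without control array 2 and intermittent array 3 these were 2009 (803 lower), 1171 (726 higher) and 311, with 1 list between the hypoxic groups. The covariate gave 1906 (683 lower) and 1185 (706 higher, 479 lower). Splitting the controls gave a mean r of 0.652, with fewer control arrays on each side. Of 12 same-number pairs 2 had deviations correlated above 0.1 and only 2 arrays matched best with their own number, so the numbers are not taken to pair the arrays. With the replicate block there were 959, 561 and 0 calls and 7, 7 and 0 lists. An offset could not be run on standardised values. Signal over background is unknown.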

Other observations

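The gene families and array positions below were chosen after the data were seen, while the counts over splits and the test of response size were set before. Of 64 measured mitochondrial ribosomal protein genes, which serve protein synthesis in mitochondria, 7 fell and 2 rose in intermittent hypoxia and 3 fell and 2 rose in chronic hypoxia, a smaller part than the 19.7% and 11.8% of all probes called. MRPL24 (-0.90 and -0.77), MRPL28 (-0.77 and -0.84) and MRPL57 (-0.64 and -0.79) fell in both, and MRPS6 (0.67 and 0.60) rose in both. The family medians were -0.09 and -0.10, at the 0.83rd and 0.21st percentile of level-matched random lists, with camera adjusted p values of 0.0262 and 0.00737, and adjusted p = 0.788 and 0.890 with an estimated correlation. Of 34 proteasome subunit genes 6 fell and 2 rose in intermittent hypoxia, with PSMB10 (-0.55) and PSMC3 (-0.55) lower and PSMC6 (0.75) and PSMD10 (0.67) higher, and 1 fell in chronic hypoxia. Their camera adjusted p values were 0.0262 and 0.00573, and adjusted p = 0.788 and 0.890 with an estimated correlation. Medians of both families were below 0 under quantile normalization and median centring too. Tests of the array means did not pass: the exact two-sided permutation p was 0.371 and 0.257 for the mitochondrial ribosomal genes (adjusted p = 0.916 and 0.857 over 30 tests) and 0.314 and 0.200 for the proteasome genes (0.916 and 0.750), so a shift of either family as a whole is not shown.

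Other single genes outside the naming rule changed as well. SELENOK, a selenoprotein of the endoplasmic reticulum, rose from 0.09 ± 0.17 to 1.19 ± 0.25 in intermittent and 1.24 ± 0.19 in chronic hypoxia (SD, n = 4 arrays each). CIRBP, the cold-inducible RNA-binding protein, fell from 0.79 ± 0.28 to -0.40 ± 0.28 and -0.09 ± 0.14. EIF4A2 (1.08, SE 0.209) and EIF4G2 (0.97, SE 0.167) rose and EIF4A1 (-0.72, SE 0.194) fell among 40 initiation factor genes in intermittent hypoxia, 8 of which rose and 4 fell, with no call of the family (camera adjusted p = 0.698). The 71 cytosolic ribosomal protein genes had a median of -0.19 in intermittent against chronic hypoxia, with 16 of 71 above 0 and 0 called, and -0.12 under quantile normalization and -0.23 after median centring. That median was lower than all 10000 matched lists, yet their array means were 4.16 ± 0.21 and 4.29 ± 0.22 (SD, n = 4 arrays each; exact two-sided permutation p = 0.400, adjusted p = 0.916 over 30 tests). camera gave an adjusted p of 3.89e-07, and adjusted p = 0.978 with an estimated correlation of 0.465 between these genes.

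Chance groupings of arrays were counted over all 35 splits of the 8 arrays of each comparison. In chronic hypoxia against control 1 of 35 splits, the real one with 803 probes in a fit of these groups alone, gave as many. The highest other split gave 0. With 35 splits no smaller share is possible, so chance is made unlikely but is not excluded. The splits also cannot tell the gas from another difference between the groups. In intermittent hypoxia against control 1 of 35 splits, the real one with 839, gave as many, and the highest other was 777. That split exchanged control array 2 with intermittent array 3 and points to a structure of the arrays beside the groups. Between the hypoxic groups all 35 splits gave at least the 0 calls of the real one, and the highest other, 342, exchanged intermittent array 3 with chronic array 3. The first component of the deviations from group means held 35.4% of their variance and had its largest weights on intermittent array 3 (0.59) and control array 2 (-0.51).

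Exchanged labels are a candidate explanation for that split. On 1120 probes called in chronic hypoxia against the other 3 control arrays, intermittent array 3 lay at 94.8% and control array 2 at 39.9% of the mean chronic response, and the other intermittent arrays at 102.5% to 106.9%. A control exchanged with a hypoxic array should lie near the hypoxic arrays, so these values argue against an exchange of either with an array of the other kind. They cannot tell an exchange of intermittent array 3 with a chronic array, which stays open: over all probes this array correlated at 0.972 to 0.986 with the chronic arrays and at 0.951 to 0.957 with the other intermittent arrays. The same position of control arrays 1, 3 and 4, each held out in turn, was 14.4%, -1.57% and 11.8%. What moved control array 2 part of the way was not tested.

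It was tested as a hypothesis that intermittent hypoxia moved responding genes further than chronic hypoxia. Over 1367 probes called for the mean of both hypoxic groups against control, the mean shift in the direction of the response was 0.632 ± 0.042 in intermittent and 0.567 ± 0.067 in chronic hypoxia (SD, n = 4 arrays each), a difference of 0.066. The exact two-sided permutation p was 0.171, where 70 regroupings allow 0.0286 as the smallest p. The test set beforehand counted such a p against the hypothesis, but a p that misses the threshold does not exclude a difference of this size with 4 arrays a group, so the hypothesis may hold and stays open. Under quantile normalization, median centring and rescaling the p was 0.200. The test cannot assign a difference, or its absence, to the pattern of hypoxia, because the O2 levels set for the groups differed too.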
